A study of Arabidopsis thaliana with 24 samples.

How the data were processed

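The measurements were messenger RNA levels in 24 strand-specific, paired-end RNA sequencing libraries made from whole seedlings of Arabidopsis thaliana. Per the labels, seedlings were 9 days old and had grown on half-strength Murashige and Skoog medium with sucrose. The wild type was Col-0 and the mutant line was exa1-1. Groups were taken from the genotype and treatment in the labels, which gave 8 groups of 3 libraries, and the series description calls the replicates biological and independent. The salt series had its own control (1/2 MS) and so did the heat series (23 °C), and all treatments lasted 60 min. The batch entry in the labels was the same for each library and was not used.

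The deposited gene counts were whole numbers per gene and library with no normalization. Per the submitters' processing notes, reads were handled with HISAT2 2.0.4, an aligner, and HTSeq 0.6.1p1, a read counter, on the genome build TAIR10. The counting mode, the strand setting, the annotation release and any filters are not given in the sources used here. Counting modes of this kind leave out reads that fit more than 1 gene, so near-identical genes can be undercounted, and without a stated strand setting, reads of overlapping antisense genes cannot be told apart. The deposited FPKM values (fragments per kilobase of gene, scaled to library size) were also the authors' own, and in each gene the ratio of count to FPKM was the product of a factor for the gene and the library's total count, so FPKM carried no further scaling. The tool that made them is not given in the sources used here. There were 32833 genes with counts and 28251 with FPKM values, and the 4582 genes found only among the counts had 0 counts in all libraries. The tables named the genes, and for 21874 of them the symbol equalled the identifier. Of all genes, 27628 were annotated as protein coding and 3481 as long non-coding RNA, and 0 lines named no gene. Coordinates came from the RefSeq annotation of TAIR10.1, in which 32548 identifiers were found.

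Totals ranged from 17658196 to 20992263 counts per library. Replicate libraries correlated across genes at 0.984 to 0.994 (log2 CPM, 24 pairs), and the chi-square statistic per gene of 1.6 to 10.3 showed that each pair differed by more than sampling noise, so no pair was taken for repeat deposits of the same library. This does not show that they are biological replicates. Reads had no molecular identifiers, so floors and intervals cover counting error only.

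Main tests used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test on the counts, TMM scaling, the default expression filter, a mean per group and Benjamini-Hochberg (BH) adjustment, with calls at an adjusted p under 0.05. There were 3 fits of 12 libraries each: the salt series, the heat series and both control sets. In each series the treatment effect was tested in both genotypes, the genotype effect in both conditions, and the difference of the treatment effects as an interaction. In the fit of the control sets, the difference between sets and its interaction with genotype were tested. Printed log2 changes are edgeR's, CPM values use the TMM-scaled library sizes, and standard errors come from log2 CPM per library with a prior count of 2. Where a group had 0 counts, a floor of 3 counts over the group gave the lower bound of a fold. Overlaps were compared with the product of independent lists, and the pairs compared this way shared no library.

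Gene lists were fixed by gene identifier before the data were examined, as were the tests, the groups and the rule for named genes. They covered EXA1 with its GYF-domain homologues, small heat shock proteins, chaperones with co-chaperones, heat shock factors, the ER unfolded protein response, ABA and osmotic response, ion transport, early stress and oxidative response, salicylic acid with NLR defence, jasmonate, ethylene, auxin, translation initiation, mRNA decay and granules, photosynthesis, root markers, seed storage, cell division, the clock, touch, and genes encoded in the chloroplast and the mitochondrion. A further list of cytosolic ribosomal proteins was to be taken from gene descriptions, which the tables did not hold, and was not analysed here. Each of the 22 lists was tested in 10 contrasts where at least 3 members were measured, which made 215 tests with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted together. Of 99 calls, 27 held with an estimated correlation.

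The rule allowed EXA1 to be named, the 10 genes with the largest increase and decrease per contrast among those with an adjusted p under 0.05, a mean of at least 1 log2 CPM and no overlap between the groups compared (10% of genes by chance for 3 libraries against 3; not required of interactions), and up to 4 members per list with the smallest adjusted p. The text prints part of the genes so allowed. No log2 change is printed for a gene with 3 or fewer counts over a group, and those of genes with under 10 (GolS2, TSPO, CRK30, BGLU34 and TPS04) depend on edgeR's prior count. For the named genes, words of 100 bases from the transcripts were counted in the genome, and LHCB2.1, LHCB2.2, BIP1 and BIP2 had under 90% of words found once.

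Alternatives were relative log expression factors or total counts in place of TMM, DESeq2 1.42.0 with its own factors, no expression filter, a fold threshold, removal of organelle genes, all 24 libraries in a single model, only the groups compared, the replicate number as a block, leaving out each library in turn, and deposited FPKM with limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries. Leaving out a pair of exa1-1 libraries at 39 °C, and leaving out libraries for the correlations, were added after seeing the data. Scripts were tested on simulated counts made from the real means and library sizes with 200 changed genes. Of 2-fold changes, 88.3% were recovered in a simulated salt response of exa1-1 and 86.7% in a simulated heat response, 76.7% and 78.3% in simulated salt and heat interactions, and 75% in the interaction of genotype with control set. Of 1.3-fold changes, 43.8%, 20% and 18.8% were recovered in these 3 interactions. In simulated interactions, 20 of 20 changed lists and 0 of 20 unchanged lists were called by camera. Simulated genes were drawn independently, so this does not test camera on lists whose members move together.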

Results

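Gene counts were compared in 24 RNA sequencing libraries from whole 9-day-old Arabidopsis thaliana seedlings of the wild type Col-0 and of the exa1-1 mutant line. EXA1 (AT5G42950) encodes a protein with a GYF domain, a module that binds proline-rich peptides. The libraries fell into a salt series and a heat series, each with both genotypes and its own unstressed control, and each of the 8 groups had 3 libraries. In the salt series, seedlings were kept for 60 min on half-strength Murashige and Skoog medium (1/2 MS) or on the same medium with 200 mM NaCl. In the heat series, they were kept for 60 min at 23 °C or 39 °C. The first principal component held 51% of the variance and separated the 39 °C libraries from the rest.

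EXA1, on chromosome 5 from 17224270 to 17231384 on the plus strand of TAIR10.1, was lower in exa1-1 libraries of all 4 conditions, which checked the genotype labels. On 1/2 MS, its mean count was 2589 ± 183 (SD, n = 3) in wild type and 732 ± 63.5 (SD, n = 3) in exa1-1, a 3.46-fold difference. Under NaCl, the means were 3215 ± 142 and 916 ± 16 (SD, n = 3 each). At 23 °C they were 4294 ± 351 and 1078 ± 92.5, and at 39 °C 2426 ± 216 and 282 ± 54.1 (SD, n = 3 each), a 4.35-fold and an 8.40-fold difference. Which part of EXA1 the reads of the mutant covered was not analysed here. The homologous GYF-domain genes AT1G24300 and AT1G27430 did not pass the test on 1/2 MS, with log2 differences of -0.10 ± 0.07 and -0.04 ± 0.07 (SE). The list of EXA1 and these homologues passed camera in each of the 4 conditions (adjusted p from 1.9e-13 to 1.85e-09, and 0.00429 to 0.0264 with an estimated correlation), but it holds the mutated gene, so this says nothing of the homologues. On 1/2 MS, under NaCl, at 23 °C and at 39 °C, 1, 1, 1 and 2 of the 3 genes fell, and at 39 °C 1 without replicate 3 of wild type or replicate 1 or 2 of exa1-1.

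**Figure D1:**
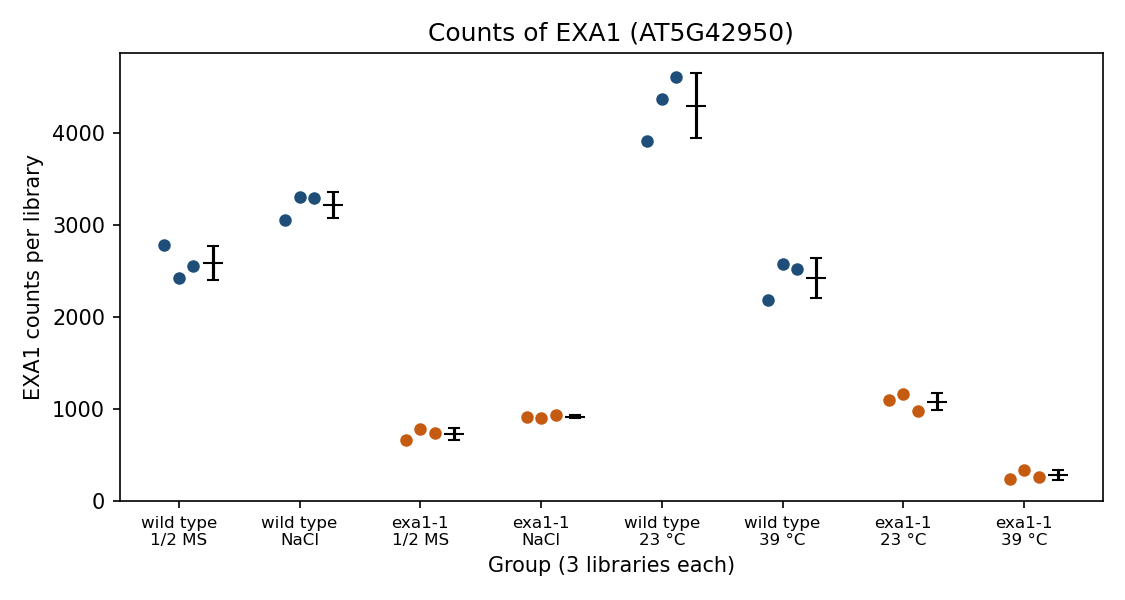
Counts of EXA1 in each library (points; blue, wild type; orange, exa1-1), with the mean and SD of the 3 libraries of each of the 8 groups (black) on a linear axis that starts at 0. The exa1-1 groups lay between 282 and 1078 counts on average and the wild-type groups between 2426 and 4294.

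The first comparison asked how wild-type seedlings responded to 60 min of salt. Genes of the abscisic acid (ABA) and osmotic response rose together: all 39 measured members were higher under NaCl (39 when adjusted over the list alone, median log2 fold change 3.71; camera adjusted p = 6.86e-97, and 0.0101 with an estimated correlation). RD29A (LTI78, AT5G52310), a marker of dehydration, rose 29.0-fold from 140 to 4073 CPM (log2 4.86 ± 0.10, SE). DREB2A (AT5G05410), a transcription factor of the dehydration response, rose 19.1-fold (4.25 ± 0.09), LEA14 (AT1G01470), a late embryogenesis abundant protein, rose 8.12-fold (3.02 ± 0.07), and HVA22D (AT4G24960) rose 6.32-fold (2.66 ± 0.06). Among the largest changes of any gene, the galactinol synthase gene GolS2 (AT1G56600) rose from 0.112 to 59.7 CPM (8.98 ± 0.32) and TSPO (AT2G47770), an ABA-induced membrane protein, rose from 0.112 to 57.2 CPM (8.91 ± 0.28). The ABA receptor gene PYL6 (AT2G40330) fell from 47.6 to 0.468 CPM (-6.66 ± 0.15), and CRK30 (AT4G11460), a receptor-like kinase, fell from 23 to 0.105 CPM (-7.71 ± 0.48). All values from this comparison carry the SE of 3 libraries in each group.

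Stress hormone and signalling genes also rose under salt in wild type. Of 18 jasmonate genes, 17 rose and 1 fell (17 and 1 over the list alone, median 1.99; camera adjusted p = 1.25e-18, and 0.016 with an estimated correlation). LOX2 (AT3G45140), the lipoxygenase of jasmonate synthesis, rose 35.1-fold (5.13 ± 0.11), AOC2 (AT3G25770), allene oxide cyclase, rose 4.81-fold (2.27 ± 0.09), and the repressor JAZ10 (AT5G13220) rose 4.38-fold (2.13 ± 0.08). Of 21 early stress and oxidative genes, 18 rose and 2 fell (18 and 2 over the list alone, camera adjusted p = 1.01e-08, and 0.016 with an estimated correlation). WRKY40 (AT1G80840) changed by 2.15 ± 0.06, the zinc finger gene ZAT12 (RHL41, AT5G59820) by 2.86 ± 0.05 and UPOX (AT2G21640) by 3.40 ± 0.18. Of 19 heat shock transcription factor genes, 17 rose and 1 fell (17 and 1 over the list alone, camera adjusted p = 7.61e-06, and 0.0103 with an estimated correlation). HSFA6B (AT3G22830) rose 127-fold (6.98 ± 0.44), HSFC1 (AT3G24520) 3.82-fold (1.94 ± 0.12) and HSFA4A (HSF_A4A, AT4G18880) 3.30-fold (1.72 ± 0.06). Of 15 ethylene genes, 9 rose and 3 fell (9 and 3 over the list alone, camera adjusted p = 0.0075; adjusted p = 0.211 with an estimated correlation). The ACC synthase genes ACS6 (AT4G11280) and ACS2 (AT1G01480) rose by 3.73 ± 0.06 and 3.59 ± 0.26.

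Endoplasmic reticulum (ER) chaperone genes moved the other way. Of 18 genes of the ER unfolded protein response, 13 fell and 4 rose (13 and 4 over the list alone, median -1.25; camera adjusted p = 3.26e-11; adjusted p = 0.132 with an estimated correlation). The lumenal chaperone genes BIP1 (AT5G28540) and BIP2 (AT5G42020) fell 3.16-fold (-1.66 ± 0.03) and 3.10-fold (-1.63 ± 0.06), and calnexin, CNX1 (AT5G61790), fell 3.96-fold (-1.99 ± 0.07). BIP1 and BIP2 share part of their sequence with each other, so the division of reads between them is uncertain. Of 13 cell division genes, 11 fell and 0 rose (11 and 0 over the list alone, camera adjusted p = 0.00973; adjusted p = 0.219 with an estimated correlation). The replication clamp gene PCNA1 (AT1G07370) changed by -1.56 ± 0.12 and the helicase gene MCM2 (AT1G44900) by -0.93 ± 0.03. Of 17 root genes, 12 fell and 4 rose (12 and 4 over the list alone, camera adjusted p = 0.00973; adjusted p = 0.123 with an estimated correlation). The root hair genes LRX1 (AT1G12040) and EXPA18 (AT1G62980) fell 18.8-fold (-4.23 ± 0.18) and 9.55-fold (-3.26 ± 0.09), PYK10 (AT3G09260), a beta-glucosidase, fell 2.33-fold (-1.22 ± 0.06), and the aquaporin gene TIP2;3 (AT5G47450) rose 7.76-fold (2.96 ± 0.19). The cell wall extensin genes EXT6 (AT2G24980), EXT13 (AT5G35190) and EXT10 (AT5G06640) were among the largest decreases, with log2 changes of -6.39 ± 0.46, -6.31 ± 0.38 and -6.27 ± 0.27.

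Of 30 photosynthesis genes, 26 rose and 2 fell under salt in wild type (26 and 3 over the list alone, median 0.83; camera adjusted p = 4.91e-07; adjusted p = 0.381 with an estimated correlation). CAB2 (AT1G29920), a chlorophyll a/b-binding protein of the light-harvesting complex, rose 13.6-fold (3.77 ± 0.09) from a low level of 5.91 CPM, and the photosystem I antenna gene LHCA2 (AT3G61470) rose 2.15-fold (1.11 ± 0.09). The other lists did not pass camera. Of 16 small heat shock protein genes, 13 rose and 1 fell (13 and 2 over the list alone, camera adjusted p = 0.0942), with HSP23.5 (AT5G51440), a mitochondrial member, at 2.19 ± 0.07 and HSP15.4 (AT4G21870) at -5.22 ± 0.17. Of 23 chaperones and co-chaperones, 8 rose and 12 fell (0.683), with the plastid disaggregase gene CLPB3 (AT5G15450) at 1.14 ± 0.07 and the cytosolic HSP90.2 (HSP81-2, AT5G56030) at -0.55 ± 0.02. Of 12 ion transport genes, 4 rose and 5 fell (0.657). The vacuolar sodium/proton exchanger genes NHX1 (AT5G27150) and NHX2 (AT3G05030) rose (1.35 ± 0.09 and 1.47 ± 0.10), and the potassium channel gene AKT1 (KT1, AT2G26650) fell (-0.73 ± 0.07). Of 22 salicylic acid and NLR defence genes, 9 rose and 5 fell (0.461). Of 17 auxin genes 5 rose and 8 fell (0.837, with a median of -0.35 but an upward direction in camera). Of 24 translation initiation genes 4 rose and 15 fell (0.155). Of 20 mRNA decay and granule genes 5 rose and 7 fell (0.596). Of 18 clock genes, 10 rose and 5 fell (0.365). Of 3 touch genes 1 rose and 2 fell (0.259). Of 41 chloroplast-encoded genes 0 rose and 6 fell (0.617). Of 13 mitochondrion-encoded genes 0 rose and 5 fell (0.374). All 3 genes of the EXA1 list rose (0.576; 3 over the list alone), with EXA1 at 0.42 ± 0.06, AT1G24300 at 0.17 ± 0.08 and AT1G27430 at 0.15 ± 0.06. All of these p-values are camera's, adjusted over 215 list tests, and adjusted over the list alone the counts differed only for chloroplast (0 and 1) and mitochondrion-encoded genes (0 and 4) besides the small heat shock proteins. Camera and the median also differed in sign for ion transport (median -0.04, camera up) and mRNA decay (median 0.02, camera down), and the mean and median for chaperones (0.02 and -0.17).

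In all, 15227 of 21462 genes tested passed in the salt comparison of wild type (edgeR quasi-likelihood test, BH-adjusted p under 0.05). Of these 7583 were higher and 7644 lower, and 2451 and 2176 by a log2 change of at least 1. With total counts as the only scaling, the median of all genes was shifted by -0.12 in this comparison, so smaller changes are relative to that choice. With that scaling the mRNA decay genes went from 5 up and 7 down to 1 and 8, 8 mitochondrion-encoded genes fell, and AT1G24300 and AT1G27430 did not pass (edgeR, adjusted p = 0.489 and 0.659). Neither passed without replicate 2 or 3 of wild type on 1/2 MS or replicate 2 of wild type under NaCl (edgeR, adjusted p from 0.0551 to 0.0979). AT1G27430 did not pass without replicate 3 of wild type under NaCl either (0.0883). Of the seed storage list 2 genes were measured in the salt series, too few for camera. Its transcripts took 0.00254% of counts in replicate 2 of wild type on 1/2 MS and at most 0.00077% in the other libraries of the series.

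The second comparison asked how exa1-1 responded to salt, and whether its response differed. In exa1-1, all 39 ABA and osmotic genes rose (39 over the list alone, median 4.14; camera adjusted p = 8.31e-103, and 0.0058 with an estimated correlation). RD29A rose 32.9-fold (5.04 ± 0.06, SE, n = 3 libraries per group) and LEA14 8.76-fold (3.13 ± 0.02). Of the heat shock factors 16 rose and 1 fell, of the early stress genes 17 rose and 3 fell, and all 18 jasmonate genes rose (16 and 1, 17 and 3, and 18 and 0 over the list alone). These calls held with an estimated correlation (camera, adjusted p = 0.0103, 0.0158 and 0.0326). HSFA6B rose 174-fold (7.45 ± 0.16), LOX2 12.2-fold (3.61 ± 0.16) and CLPB3 2.15-fold (1.11 ± 0.04), whereas PYL6 fell by 6.56 ± 0.13 and BIP1 fell by 1.15 ± 0.01 on the log2 scale. Of the ER genes 4 rose and 12 fell (camera adjusted p = 1.6e-05; adjusted p = 0.283 with an estimated correlation). Of the cell division genes 0 rose and 12 fell (camera adjusted p = 0.000397; adjusted p = 0.155 with an estimated correlation). Of the ethylene genes 10 rose and 3 fell (camera adjusted p = 0.000157, and adjusted p = 0.123 with an estimated correlation), and of the root genes 5 rose and 12 fell (0.00372, and adjusted p = 0.119 with an estimated correlation). Photosynthesis genes (22 rose, 5 fell) and small heat shock protein genes (13 rose, 1 fell) passed camera as well (adjusted p = 0.0324 and 0.0252). With an estimated correlation both lost the call (camera, adjusted p = 0.75 and 0.564). Adjusted over the list alone, the counts of all lists that lost the call were the same. In total 15428 genes passed in exa1-1 (edgeR quasi-likelihood test, BH), 7667 higher and 7761 lower. Across the 21462 genes, the log2 fold changes of both genotypes correlated at 0.936 (Pearson) and 0.914 (Spearman), with a slope of 1.08 for exa1-1 on wild type; genes are not independent replicates.

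The difference of the salt responses was tested directly as an interaction, and 2401 genes passed (edgeR quasi-likelihood test, BH). The response was higher in exa1-1 at 1293 and lower at 1108, of which 149 and 135 differed by at least 1 on the log2 scale. Chaperone genes responded more positively in exa1-1: 12 of 23 were higher and 0 lower (15 and 0 over the list alone, camera adjusted p = 9.37e-14, and 0.0103 with an estimated correlation). HSP70 (AT3G12580), a cytosolic chaperone, rose 2.30-fold in exa1-1 (1.20 ± 0.01) and responded by 0.70 ± 0.06 more than in wild type (SE, n = 3 libraries in each of 4 groups). For the co-chaperone gene HOP3 (AT4G12400) the difference was 0.71 ± 0.06. Of the 18 ER genes, 13 had a higher response and 0 a lower one (16 and 0 over the list alone, camera adjusted p = 7.77e-13; adjusted p = 0.123 with an estimated correlation). BIP1 differed by 0.51 ± 0.03 and CNX1 by 0.52 ± 0.08. Of the 39 ABA genes, 13 responded more and 0 less (20 and 1 over the list alone, camera adjusted p = 3.85e-09; adjusted p = 0.29 with an estimated correlation). The phosphatase gene ABI1 (AT4G26080) differed by 0.74 ± 0.10 and the dehydrin gene ERD10 (AT1G20450) by 0.65 ± 0.13. Without replicate 1 of wild type under NaCl, 23 ABA genes passed. Photosynthesis genes responded less: 0 of 30 were higher and 20 lower (1 and 24 over the list alone, camera adjusted p = 1.52e-17; adjusted p = 0.156 with an estimated correlation). CAB2 differed by -1.37 ± 0.19 and the Rubisco small subunit gene RBCS1A (AT1G67090) by -0.59 ± 0.10.

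Some hormone lists differed as well. Auxin and ethylene genes were lower in exa1-1 on 1/2 MS (median log2 difference -1.38 and -0.39) and less so under NaCl (-0.64 and -0.08). GH3.3, PIF4 and SAG13 started lower in exa1-1 too. Of 15 ethylene genes 7 had a higher and 0 a lower response in exa1-1 (8 and 0 over the list alone, camera adjusted p = 2.63e-05; adjusted p = 0.0823 with an estimated correlation). The F-box gene EBF2 (AT5G25350) differed by 0.80 ± 0.10. Of 17 auxin genes 5 were higher and 0 lower (5 and 1 over the list alone, camera adjusted p = 0.00102; adjusted p = 0.224 with an estimated correlation). GH3.3 (AT2G23170), which conjugates auxin to amino acids, differed by 1.44 ± 0.24. Of 22 salicylic acid and NLR genes 0 were higher and 7 lower (2 and 7 over the list alone, camera adjusted p = 0.0246; adjusted p = 0.509 with an estimated correlation). The transcription factor gene SARD1 (AT1G73805) differed by -1.11 ± 0.28. Of 18 clock genes 5 were higher and 0 lower (5 and 0 over the list alone, camera adjusted p = 0.000982; adjusted p = 0.366 with an estimated correlation). PIF4 (AT2G43010) differed by 1.3 ± 0.22. Of 13 cell division genes 0 were higher and 3 lower (0 and 3 over the list alone, camera adjusted p = 0.000808; adjusted p = 0.155 with an estimated correlation). Of 18 jasmonate genes 5 were higher and 5 lower (6 and 5 over the list alone, camera adjusted p = 0.872). LOX2 differed by -1.52 ± 0.20. The count of salicylic acid and NLR genes was 4 without replicate 2 of exa1-1 on 1/2 MS or replicate 1 of exa1-1 under NaCl. Outside the lists, the defence gene ACD6 (AT4G14400, -2.56 ± 0.65) and SAG13 (AT2G29350, 2.43 ± 0.45), a senescence-associated dehydrogenase gene, were among the largest differences, although ACD6 did not pass with FPKM values and limma (adjusted p = 0.0528).

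**Figure D2:**
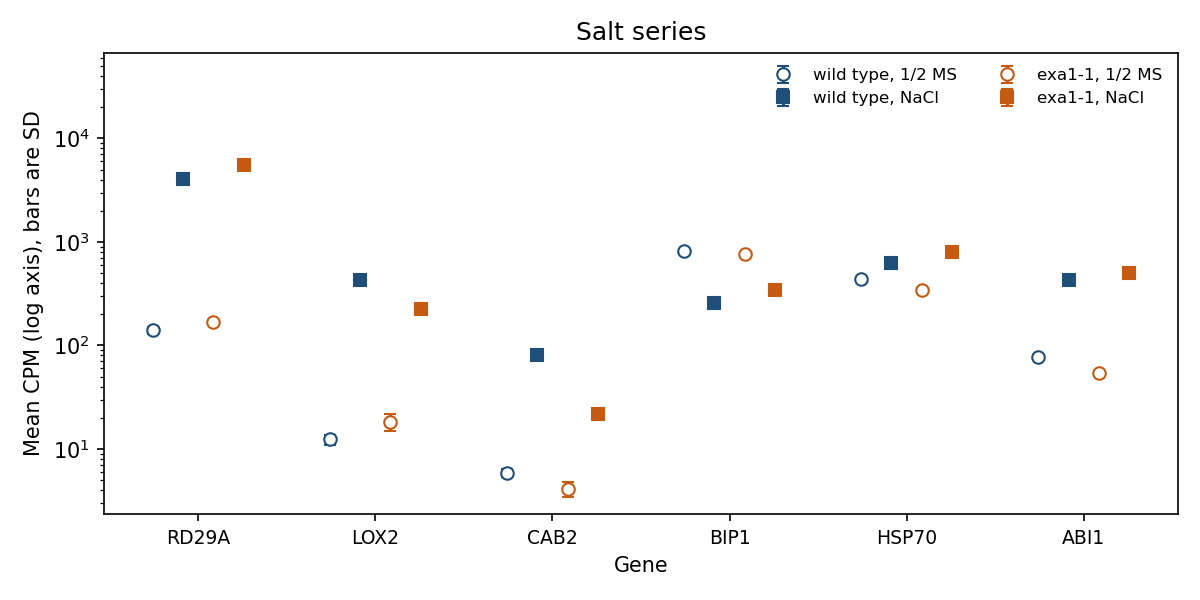
Mean CPM (log axis) of 6 genes in the 4 groups of the salt series (open circles, 1/2 MS; filled squares, NaCl; blue, wild type; orange, exa1-1), with the SD of 3 libraries as bars. RD29A (LTI78) rose in both genotypes, to 4073 CPM in wild type and 5518 in exa1-1. LOX2 and CAB2 reached lower levels under NaCl in exa1-1 (223 and 21.5 CPM) than in wild type (433 and 80.5 CPM), and BIP1 fell to 258 CPM in wild type and 344 in exa1-1.

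The next comparison asked how exa1-1 differed from wild type in the salt series, first on 1/2 MS. Auxin genes were lower in exa1-1: 14 of 17 fell and 0 rose (17 and 0 over the list alone, median -1.38; camera adjusted p = 2.29e-28, and 0.0047 with an estimated correlation). IAA2 (AT3G23030) and IAA19 (AT3G15540), auxin-induced repressors, were 2.20-fold (-1.13 ± 0.05, SE, n = 3 libraries per group) and 2.61-fold (-1.38 ± 0.20) lower, and GH3.3 was 3.44-fold lower (-1.78 ± 0.19). Of 15 ethylene genes 8 fell and 0 rose (10 and 0 over the list alone, camera adjusted p = 1.63e-10, and 0.0146 with an estimated correlation). ERF2 (AT5G47220) differed by -1.05 ± 0.11. Of 3 touch genes 2 fell (3 over the list alone, camera adjusted p = 2.13e-07, and 0.00828 with an estimated correlation), with TCH4 (AT5G57560), a cell wall enzyme, at -0.76 ± 0.06. The plant defensin genes PDF1.2 (AT5G44420), PDF1.3 (AT2G26010) and PDF1.2c (AT5G44430), antifungal peptides, were 29.6-fold (4.88 ± 0.62), 28.8-fold (4.85 ± 0.56) and 22.0-fold (4.46 ± 0.42) higher in exa1-1. The methyltransferase gene AT1G73600 was 4.70-fold higher (2.23 ± 0.42), whereas AT1G26390, of the berberine bridge enzyme family, and SAG13 were 12.6-fold (-3.65 ± 0.51) and 9.68-fold (-3.27 ± 0.44) lower.

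Further lists that passed camera on 1/2 MS lost that call with an estimated correlation. Of 30 photosynthesis genes 22 fell and 0 rose (25 and 1 over the list alone, camera adjusted p = 8.53e-19; adjusted p = 0.155 with an estimated correlation). RBCS2B (AT5G38420) and CAB3 (AT1G29910) differed by -0.84 ± 0.06 and -0.74 ± 0.06. Of 16 small heat shock protein genes 9 fell and 0 rose (9 and 0 over the list alone, camera adjusted p = 3.15e-06; adjusted p = 0.219 with an estimated correlation). Of 23 chaperone genes 9 fell and 1 rose (10 and 1 over the list alone, camera adjusted p = 0.000141; adjusted p = 0.132 with an estimated correlation). Hsp70-2 (AT5G02490) differed by -0.56 ± 0.06. The heat shock factor gene HSFA2 (AT2G26150) was 2.09-fold lower (-1.07 ± 0.08). Of 22 salicylic acid and NLR genes 11 fell and 1 rose (12 and 1 over the list alone, camera adjusted p = 3.46e-05; adjusted p = 0.224 with an estimated correlation). Of 18 ER genes 6 fell and 1 rose (8 and 2 over the list alone, camera adjusted p = 0.00332; adjusted p = 0.475 with an estimated correlation). Of 18 clock genes 5 fell and 1 rose (6 and 1 over the list alone, camera adjusted p = 0.00203; adjusted p = 0.385 with an estimated correlation). PIF4 differed by -1.17 ± 0.13. Of 39 ABA genes 10 fell and 4 rose (10 and 4 over the list alone, camera adjusted p = 0.0344; adjusted p = 0.75 with an estimated correlation). COR15A (AT2G42540), a chloroplast-targeted cold protein, was 3.43-fold higher (1.78 ± 0.31). Of 17 root genes 5 rose and 1 fell (5 and 1 over the list alone, camera adjusted p = 0.0143; adjusted p = 0.155 with an estimated correlation). The nitrate transporter gene NRT2:1 (AT1G08090) differed by 0.97 ± 0.12. In total 3920 genes passed (edgeR quasi-likelihood test, BH), 1747 higher and 2173 lower in exa1-1.

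Under NaCl, photosynthesis genes were lower in exa1-1: 28 of 30 fell and 0 rose (28 and 0 over the list alone, median -0.56; camera adjusted p = 9.1e-56, and 0.0168 with an estimated correlation). CAB2 was 3.74-fold lower (-1.90 ± 0.10, SE, n = 3 libraries per group) and the Rubisco activase gene RCA (AT2G39730) 2.05-fold lower (-1.04 ± 0.06). Of 22 salicylic acid and NLR genes 14 fell and 1 rose (15 and 2 over the list alone, camera adjusted p = 4.88e-09; adjusted p = 0.123 with an estimated correlation). The glucanase gene PR2 (BGL2, AT3G57260) was 10.9-fold lower (-3.45 ± 0.26), FMO1 (AT1G19250), of systemic acquired resistance, 5.21-fold lower (-2.38 ± 0.22) and SARD1 2.43-fold lower (-1.28 ± 0.08). Of 17 auxin genes 11 fell and 0 rose (11 and 0 over the list alone, camera adjusted p = 1.62e-07; adjusted p = 0.0823 with an estimated correlation). Of 18 jasmonate genes 7 fell and 3 rose (10 and 4 over the list alone, camera adjusted p = 0.0473; adjusted p = 0.564 with an estimated correlation). LOX2 differed by -0.96 ± 0.06. Of 39 ABA genes 19 rose and 2 fell (20 and 2 over the list alone, camera adjusted p = 1.51e-06; adjusted p = 0.386 with an estimated correlation). COR15A differed by 1.19 ± 0.12 and RD29B (LTI65, AT5G52300) by 1.41 ± 0.27. Of the ER genes 10 rose and 1 fell (11 and 1 over the list alone, camera adjusted p = 0.000182; adjusted p = 0.359 with an estimated correlation). BIP1 differed by 0.42 ± 0.02. Of the chaperones 10 rose and 0 fell (12 and 0 over the list alone, camera adjusted p = 0.000541; adjusted p = 0.155 with an estimated correlation). HOP3 differed by 0.52 ± 0.04. Of 24 translation initiation genes 9 rose and 0 fell (9 and 0 over the list alone, camera adjusted p = 0.024; adjusted p = 0.374 with an estimated correlation). Of 3 touch genes 0 rose and 2 fell (1 and 2 over the list alone, camera adjusted p = 0.0376; adjusted p = 0.178 with an estimated correlation). PDF1.3 and PDF1.2 were 10.7-fold (3.42 ± 0.09) and 7.38-fold (2.88 ± 0.10) higher, and ACD6 and AT1G26390 were 12.1-fold (-3.60 ± 0.30) and 32.2-fold (-5.01 ± 0.45) lower. In total 6321 genes passed (edgeR quasi-likelihood test, BH), 3406 higher and 2915 lower in exa1-1. The count of translation initiation genes was 5, 5 and 4 without replicate 1, 2 or 3 of exa1-1 under NaCl.

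The heat comparison asked how wild-type seedlings responded to 60 min at 39 °C. Molecular chaperone genes rose by the largest factors. Of 16 small heat shock protein genes 15 rose and 0 fell (15 and 0 over the list alone, median 14.24; camera adjusted p = 4.28e-130, and 0.00176 with an estimated correlation). HSP18.2 (AT5G59720) rose from 0.273 to 10430 CPM (15.23 ± 0.29, SE, n = 3 libraries per group), AT1G07400 from 0.716 to 15540 CPM (14.39 ± 0.06) and AT1G54050 from 2.20 to 2745 CPM (10.28 ± 0.06). All 23 chaperones and co-chaperones rose (23 over the list alone, median 5.38; camera adjusted p = 3.44e-93, and 0.00176 with an estimated correlation). HSP101 (AT1G74310), the disaggregase of heat tolerance, rose from 13.4 to 15880 CPM (1185-fold, 10.21 ± 0.08), Hsp70b (AT1G16030) 2032-fold (10.99 ± 0.08), HSP90.1 (AT5G52640) 1077-fold (10.07 ± 0.05) and the co-activator gene MBF1C (AT3G24500) 382-fold (8.58 ± 0.06). Small heat shock protein and chaperone genes together took 0.336% of all counts in wild type at 23 °C and 17.1% at 39 °C.

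Of 19 heat shock factor genes 13 rose and 1 fell (13 and 1 over the list alone, camera adjusted p = 2.85e-13, and 0.00241 with an estimated correlation). HSFA2 rose 6655-fold (12.70 ± 0.15) and HSFB1 (HSF4, AT4G36990) 25.4-fold (4.67 ± 0.06). Of 18 ER genes 17 rose and 0 fell (17 and 0 over the list alone, median 1.97; camera adjusted p = 3.06e-19, and 0.00475 with an estimated correlation). The co-chaperone gene ERDJ3A (AT3G08970) rose 254-fold (7.99 ± 0.16), BIP1 and BIP2 17.9-fold (4.16 ± 0.08) and 23.9-fold (4.58 ± 0.08), and CNX1 10.7-fold (3.42 ± 0.04). All 30 photosynthesis genes rose (30 over the list alone, median 2.18; camera adjusted p = 5.54e-20; adjusted p = 0.0994 with an estimated correlation). CAB2 rose 46.6-fold (5.54 ± 0.11), and LHCB2.1 (AT2G05100) and LHCB2.2 (AT2G05070) rose 29.5-fold (4.88 ± 0.07) and 11.3-fold (3.50 ± 0.07). This pair shares sequence, so its reads are uncertain. Of 38 ABA and osmotic genes 29 rose and 3 fell (29 and 3 over the list alone, camera adjusted p = 9.24e-11; adjusted p = 0.155 with an estimated correlation). The galactinol synthase gene GolS1 (AT2G47180) rose 261-fold (8.03 ± 0.08) and DREB2A 98.4-fold (6.62 ± 0.05). Of 152 mitochondrion-encoded genes 32 passed the expression filter, and of these 31 rose and 0 fell (31 and 0 over the list alone, camera adjusted p = 8e-06, adjusted p = 0.316 with an estimated correlation). Their median was 4.45, and 4.18 with 3 genes that had 0 counts in a group set to the bound that 3 counts allow. Among them were cox1 (ATMG01360), a subunit of cytochrome c oxidase, from 0.581 to 18.3 CPM (4.94 ± 0.26), and ATMG00020 from 41.1 to 512 CPM (3.64 ± 0.19). The list took 0.0198% of counts at 23 °C and 0.0982% at 39 °C in wild type. Ribosomal RNA took 0.0273% and 0.0917%, of which mitochondrial rRNA, in the list too, made up 0.0186% and 0.0873%, and nuclear rRNA 0.00852% and 0.00404%. Of its 10 genes that could be matched to the reference by symbol, cox1, nad4L (ATMG00650) and rps3 (ATMG00090) shared 0.901%, 5.13% and 6.95% of 31-base words with the nuclear genome and the others 9.16% to 100%.

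**Figure D3:**
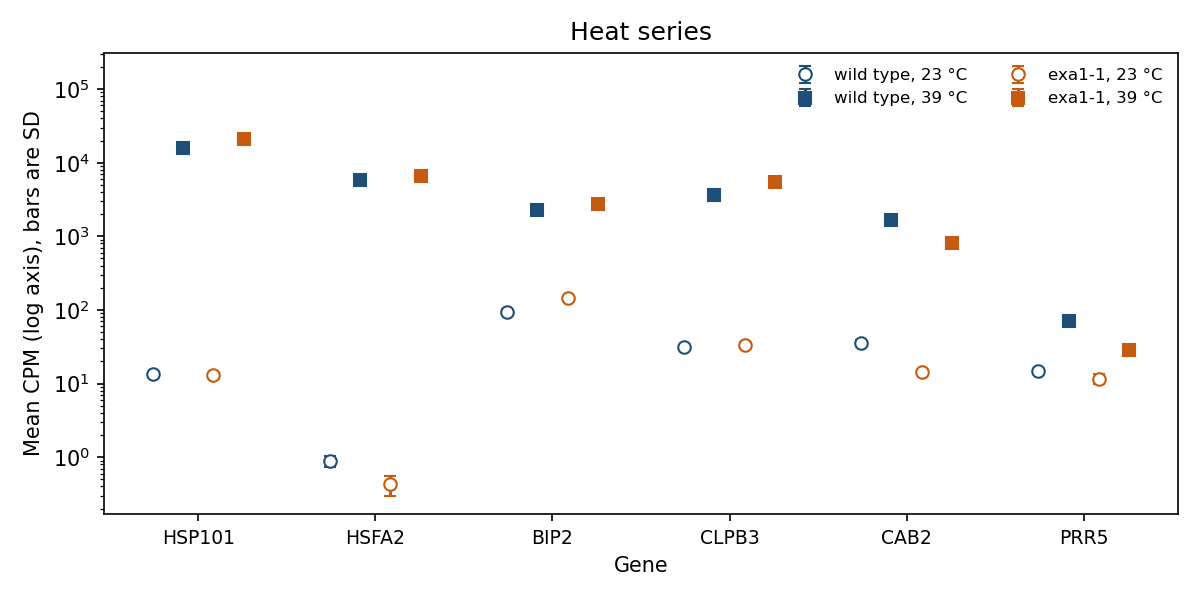
Mean CPM (log axis) of 6 genes in the 4 groups of the heat series (open circles, 23 °C; filled squares, 39 °C; blue, wild type; orange, exa1-1), with the SD of 3 libraries as bars. HSP101 rose from 13.4 to 15880 CPM in wild type and from 12.9 to 20700 CPM in exa1-1, and the clock gene PRR5 reached 70.4 CPM at 39 °C in wild type and 28.8 CPM in exa1-1.

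The auxin, root and ion transport lists did not pass camera at 39 °C. Of 15 auxin genes 12 fell and 1 rose (camera, adjusted p = 0.0631), with the auxin efflux carrier gene PIN3 (AT1G70940) at -3.27 ± 0.17. Of 17 root genes 10 fell and 2 rose (0.0551), with PYK10 at -1.97 ± 0.02 and the transcription factor gene SHR (AT4G37650) at -2.62 ± 0.17. Of 12 ion transport genes 8 fell and 1 rose (0.0537), with AKT1 at -1.48 ± 0.06 and NHX2 at 2.25 ± 0.13. Of the largest decreases, BGLU34 (AT1G47600), a beta-glucosidase, fell from 22.1 to 0.196 CPM (-6.76 ± 0.68) and the expansin gene EXPA8 (AT2G40610) from 11.8 to 0.273 CPM (-5.41 ± 0.49). Of 19 early stress genes 11 rose and 6 fell (11 and 6 over the list alone, camera adjusted p = 0.000899; adjusted p = 0.277 with an estimated correlation). The alternative oxidase gene AOX1A (AT3G22370) changed by 4.30 ± 0.07. Of 24 translation initiation genes 19 rose and 4 fell (19 and 4 over the list alone, camera adjusted p = 0.0314; adjusted p = 0.33 with an estimated correlation), with eIFiso4G2 (AT2G24050) at 2.92 ± 0.10 and EIF3C (AT3G56150) at 1.14 ± 0.03. With total counts as the only scaling 5 rose and 17 fell. The direction of further lists, none of which passed camera, also turned with that scaling. Jasmonate genes went from 10 up and 2 down (AOC2, 3.59 ± 0.13) to 6 up and 8 down, and ethylene genes from 7 and 4 (ERF104, AT5G61600, -2.48 ± 0.24) to 3 and 8. Clock genes went from 9 and 4 (10 and 5 over the list alone) to 7 and 10, with GI (AT1G22770) at 3.35 ± 0.08 and PRR5 (AT5G24470) at 2.26 ± 0.07. Chloroplast-encoded genes went from 12 up and 11 down to 5 and 19 with that scaling, and touch genes from 2 and 1 to 1 and 2. Of 20 mRNA decay genes 6 rose and 11 fell (0.34), with DCP5 (AT1G26110) at -0.91 ± 0.08 and the deadenylase gene CAF1a (AT3G44260) at -3.17 ± 0.21. Of 20 salicylic acid and NLR genes 6 rose and 9 fell (0.657), with NPR1 (AT1G64280) at 1.44 ± 0.06 and CBP60G (AT5G26920) at -1.40 ± 0.13. The mean and median of the salicylic acid list differed in sign (0.07 and -0.13). The chloroplast-encoded list did not pass (39 genes; 0.837). Of 13 cell division genes 3 rose and 4 fell (3 and 3 over the list alone, 0.752). Of 4 seed storage genes 0 rose and 4 fell (0.565). Of 3 touch genes TCH3 (AT2G41100) rose (2.92 ± 0.08) and TCH4 fell (-2.91 ± 0.15). Adjusted over the list alone, the counts printed here without such a value were the same. EXA1 itself did not pass the test in wild type (0.14 ± 0.05; edgeR quasi-likelihood test, BH-adjusted p = 0.102), and its homologue AT1G27430 rose (0.59 ± 0.04). With total counts alone both fell (-0.74 and -0.29; edgeR, adjusted p = 4.54e-08 and 0.00023).

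In all, 16791 of 20972 genes passed in wild type at 39 °C (edgeR quasi-likelihood test, BH), 8063 higher and 8728 lower, and 3599 and 5143 of them by a log2 change of at least 1. Directions of small changes depended on the scaling: with total counts alone the median of all genes was shifted by -0.88, and 3049 genes were called higher and 15202 lower, so 16.7% rather than 48.0% of the calls were higher. With that scaling 21 ABA genes rose and 12 fell, and of the heat shock factors 10 and 7, the ER genes 12 and 2, the early stress genes 10 and 9, the salicylic acid genes 3 and 13, the cell division genes 1 and 10, and the mRNA decay genes 0 and 20. Changes above use trimmed mean of M values (TMM) scaling.

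In exa1-1 at 39 °C, small heat shock protein genes (15 rose, 1 fell), chaperones (23 and 0; median 5.89), heat shock factors (13 and 3) and ER genes (16 and 0) passed camera with the same counts over the list alone. These calls held with an estimated correlation (camera, adjusted p = 0.00176, 0.00176, 0.00277 and 0.0068). HSP101 rose 1597-fold (10.64 ± 0.08, SE, n = 3 libraries per group), Hsp70b 2651-fold (11.37 ± 0.10), BIP1 16.5-fold (4.05 ± 0.05) and CAB2 57.0-fold (5.83 ± 0.07), and PIN3 fell by 3.20 ± 0.13. HSFA2 rose from 0.428 to 6696 CPM (13.91 ± 0.24). EXA1 fell in exa1-1 (-0.81 ± 0.17). Of 30 photosynthesis genes 28 rose and 0 fell (camera adjusted p = 1.25e-18; adjusted p = 0.112 with an estimated correlation). Of 38 ABA genes 29 rose and 6 fell (camera adjusted p = 3.11e-09; adjusted p = 0.15 with an estimated correlation). All 32 mitochondrion-encoded genes that passed the filter rose (median 4.20; camera adjusted p = 6.23e-06; adjusted p = 0.246 with an estimated correlation). Of 24 translation initiation genes 18 rose and 3 fell (3 and 18 with total counts alone; camera adjusted p = 0.00989; adjusted p = 0.236 with an estimated correlation). Of the early stress genes 12 rose and 6 fell (camera adjusted p = 6e-04; adjusted p = 0.236 with an estimated correlation). Of 17 root genes 1 rose and 11 fell (camera adjusted p = 0.0277; adjusted p = 0.368 with an estimated correlation), with the same counts over the list alone for each of these lists. In total 16819 genes passed (edgeR quasi-likelihood test, BH), 8047 higher and 8772 lower; with total counts alone the median of all genes was shifted by -0.995, with 2588 higher and 16089 lower. With that scaling 22 ABA genes rose and 14 fell, and of the heat shock factors 11 and 6, the ER genes 12 and 5, and the early stress genes 10 and 9. Across genes, the responses of both genotypes correlated at 0.941 (Pearson) and 0.948 (Spearman), with a slope of 1.00.

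The difference of the heat responses was tested as an interaction, and 1687 genes passed (edgeR quasi-likelihood test, BH), 914 with a higher and 773 with a lower response in exa1-1. Among chaperones 7 of 23 were higher and 0 lower (10 and 2 over the list alone, camera adjusted p = 0.000175; adjusted p = 0.287 with an estimated correlation). HOP3 differed by 0.69 ± 0.10 (SE, n = 3 libraries in each of 4 groups) and CLPB3 by 0.50 ± 0.11. With total counts alone 4 chaperones were higher and 2 lower. Of 19 heat shock factors 5 were higher and 0 lower (6 and 2 over the list alone, camera adjusted p = 0.0445; adjusted p = 0.182 with an estimated correlation). HSFA7A (AT3G51910) differed by 0.90 ± 0.13 and HSFA2 by 1.21 ± 0.28, and with total counts alone 3 of the list were higher and 3 lower. Of 18 ER genes 3 were higher and 6 lower (3 and 10 with total counts alone, 3 and 8 over the list alone, camera adjusted p = 0.0185; adjusted p = 0.287 with an estimated correlation). The membrane-bound transcription factor gene bZIP28 (AT3G10800) differed by 0.46 ± 0.05 and the disulfide isomerase gene PDIL1-2 (AT1G77510) by -0.60 ± 0.09. The median of the ER list was -0.21 and its mean 0.05. Of 17 jasmonate genes 0 were higher and 3 lower (0 and 4 over the list alone, camera adjusted p = 0.00301; adjusted p = 0.228 with an estimated correlation). OPR3 (AT2G06050), an enzyme of jasmonate synthesis, differed by -0.63 ± 0.12. EXA1 differed by -0.95 ± 0.18, RD29A by -1.53 ± 0.39, AOX1A by -0.70 ± 0.13, PRR5 by -0.96 ± 0.16 and PR2 by -4.35 ± 0.97. Of 12 ion transport genes 1 was higher and 0 lower (2 and 1 over the list alone, camera adjusted p = 0.0373; adjusted p = 0.219 with an estimated correlation). Of 20 mRNA decay genes 2 were higher and 0 lower, and 0 and 0 with total counts alone (3 and 0 over the list alone, camera adjusted p = 0.0249; adjusted p = 0.277 with an estimated correlation). Of EXA1 and its homologues 0 were higher and 1 lower (1 and 2 over the list alone, camera adjusted p = 0.0278; adjusted p = 0.211 with an estimated correlation). Of 4 seed storage genes 3 were higher and 0 lower (4 and 0 over the list alone, camera adjusted p = 0.000719; adjusted p = 0.243 with an estimated correlation). Seed storage transcripts took 0.00551% and 0.00357% of counts in replicates 2 and 3 of exa1-1 at 39 °C and 2.14e-05% in replicate 1. With total counts alone 403 genes were higher and 1563 lower, so 20.5% rather than 54.2% of the calls were higher. The count of calls was 965 and 1092 without replicate 3 or 1 of wild type at 23 °C and 1043 without replicate 3 of exa1-1 at 39 °C. Of the chaperones 4 were called without replicate 1 of wild type or replicate 1 of exa1-1 at 23 °C, or replicate 3 of wild type or replicate 2 of exa1-1 at 39 °C, and 3 without replicate 3 of wild type at 23 °C or replicate 3 of exa1-1 at 39 °C. Of the heat shock factors 3 were called without replicate 1 of wild type or of exa1-1 at 23 °C or replicate 3 of wild type at 39 °C, and 8 without replicate 3 of exa1-1 at 23 °C. Of the ER genes 5 were called without replicate 3 of wild type at 23 °C, of wild type at 39 °C or of exa1-1 at 39 °C. Jasmonate genes went to 5 without replicate 3 of exa1-1 at 23 °C and ion transport genes to 2 without replicate 1 of exa1-1 at 39 °C. Of the mRNA decay genes 1 was called without any 1 library at 23 °C, and also without replicate 3 of wild type or replicate 2 or 3 of exa1-1 at 39 °C. Of the seed storage genes 0 were called without replicate 2 of wild type at 23 °C or 3 at 39 °C, and 1 without replicate 2 of exa1-1 at 23 °C, replicate 2 of wild type at 39 °C, or replicate 2 or 3 of exa1-1 at 39 °C. HSFA2 did not pass without replicate 2 of wild type or replicate 1 of exa1-1 at 23 °C (edgeR, adjusted p = 0.0548 and 0.0556). Without both exa1-1 libraries that held the seed storage transcripts, an alternative chosen after seeing the data, 525 genes passed, and CLPB3, HSFA2 and PR2 did not (edgeR, adjusted p = 0.124, 0.0624 and 0.0778). That group then held 1 library, and the values were 0.44, 1.13 and -3.66.

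At 23 °C, auxin genes were again lower in exa1-1: 9 of 15 fell and 0 rose (10 and 0 over the list alone, median -0.99; camera adjusted p = 1.94e-10, and 0.00305 with an estimated correlation). IAA2 was 1.99-fold lower (-0.99 ± 0.01, SE, n = 3 libraries per group). ER genes were higher: 12 of 18 rose and 3 fell (12 and 3 over the list alone, median 0.37; camera adjusted p = 2.01e-08, and 0.0335 with an estimated correlation). BIP1, BIP2 and the calreticulin gene CRT1a (AT1G56340) differed by 0.60 ± 0.06, 0.61 ± 0.07 and 0.48 ± 0.07. On 1/2 MS the ER list had gone the other way, with 6 down and 1 up. Chaperones had 1 up and 9 down there, but 9 and 3 at 23 °C (camera, adjusted p = 0.0577). The median of small heat shock proteins was -0.58 there and 0.55 at 23 °C (camera, 0.154). PDF1.3 and PDF1.2 were 32.3-fold (5.01 ± 0.46) and 23.7-fold (4.57 ± 0.52) higher, and the dehydration gene RD22 (AT5G25610) was 1.77-fold higher (0.83 ± 0.11). FMO1, TIP2;3 and AT1G26390 were 4.20-fold (-2.07 ± 0.29), 3.88-fold (-1.96 ± 0.20) and 6.28-fold (-2.65 ± 0.19) lower. Of 30 photosynthesis genes 15 fell and 0 rose (17 and 0 over the list alone, camera adjusted p = 1.37e-12; adjusted p = 0.155 with an estimated correlation), with CAB2 2.52-fold lower (-1.33 ± 0.10). Of 18 clock genes 9 fell and 0 rose (10 and 0 over the list alone, camera adjusted p = 1.16e-05; adjusted p = 0.179 with an estimated correlation). PIF5 (PIL6, AT3G59060) differed by -0.93 ± 0.13. Of 20 salicylic acid and NLR genes 8 fell and 1 rose (8 and 1 over the list alone, camera adjusted p = 0.000118; adjusted p = 0.233 with an estimated correlation). Of 14 ethylene genes 4 fell and 0 rose (6 and 0 over the list alone, camera adjusted p = 0.015; adjusted p = 0.219 with an estimated correlation). Of 3 touch genes 2 fell (3 over the list alone, camera adjusted p = 0.00642; adjusted p = 0.219 with an estimated correlation). TCH4 differed by -1.14 ± 0.28. Of 13 cell division genes 3 rose (3 over the list alone, camera adjusted p = 0.00786; adjusted p = 0.366 with an estimated correlation). In total 4077 genes passed (edgeR, BH), 1735 higher and 2342 lower, and 2730 and 1575 with total counts alone (63.4% rather than 42.6% higher). Without replicate 1 or 3 of wild type at 23 °C, 2482 and 2525 genes were called. Of the cell division genes 1 and 5 were called without replicate 1 or 2 of wild type, and of the touch genes 1 without replicate 1 or 3 of wild type or replicate 1 of exa1-1.

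At 39 °C, chaperone genes were higher in exa1-1: 19 of 23 rose and 2 fell (19 and 2 over the list alone, median 0.33; camera adjusted p = 3.67e-10; adjusted p = 0.123 with an estimated correlation). CLPB3 and the mitochondrial CLPB4 (AT2G25140) were 1.52-fold (0.60 ± 0.08, SE, n = 3 libraries per group) and 1.56-fold (0.64 ± 0.11) higher. HSFA7A was higher (0.66 ± 0.07) and HSFA3 (AT5G03720) lower (-0.61 ± 0.09). Of 30 photosynthesis genes 19 fell and 0 rose (22 and 0 over the list alone, camera adjusted p = 1.5e-15; adjusted p = 0.123 with an estimated correlation). Of 18 clock genes 9 fell and 0 rose (9 and 0 over the list alone, camera adjusted p = 1.83e-06; adjusted p = 0.155 with an estimated correlation), with PRR5 2.45-fold lower (-1.29 ± 0.07). Of 20 salicylic acid and NLR genes 10 fell and 1 rose (10 and 1 over the list alone, camera adjusted p = 7.17e-05; adjusted p = 0.228 with an estimated correlation). PR2 was 13.7-fold lower (-3.78 ± 0.52) and WRKY70 (AT3G56400) 2.95-fold lower (-1.56 ± 0.29). Of 38 ABA genes 16 fell and 3 rose (16 and 3 over the list alone, camera adjusted p = 0.00223; adjusted p = 0.466 with an estimated correlation). Of 24 translation initiation genes 11 rose and 2 fell (6 and 2 with total counts alone, 11 and 2 over the list alone, camera adjusted p = 0.0111; adjusted p = 0.244 with an estimated correlation). Of 20 mRNA decay genes 7 rose and 1 fell (7 and 1 over the list alone, camera adjusted p = 0.0152; adjusted p = 0.243 with an estimated correlation). Of 18 ER genes 5 rose and 0 fell (8 and 0 over the list alone, camera adjusted p = 0.00884; adjusted p = 0.244 with an estimated correlation). Of the small heat shock proteins 4 rose and 1 fell (camera adjusted p = 0.0174; adjusted p = 0.555 with an estimated correlation). Of the ethylene genes 2 rose and 6 fell (3 and 7 over the list alone, camera adjusted p = 0.0376; adjusted p = 0.277 with an estimated correlation). Touch genes (0 rose, 2 fell) and the 4 seed storage genes (4 rose) passed camera as well (adjusted p = 0.00301 and 0.0154). With an estimated correlation these lists lost the call too (camera, adjusted p = 0.199 and 0.395). Adjusted over the list alone, the counts of small heat shock, touch and seed storage genes were the same. Leaving out 1 library moved some list counts by over 1.5 times: small heat shock proteins to 8 without replicate 1 of wild type, ethylene genes to 4 and 5 without replicate 2 of wild type or 1 of exa1-1, touch genes to 1 without replicate 1 of exa1-1, and mRNA decay and seed storage genes to 5 and 2 without replicate 2 of exa1-1. PDF1.2 was 11.3-fold higher (3.50 ± 0.29), EXT13 7.47-fold higher (2.90 ± 0.10) and the catalase gene CAT2 (AT4G35090) 1.80-fold lower (-0.85 ± 0.07). In total 5121 genes passed (edgeR quasi-likelihood test, BH), 2658 higher and 2463 lower, and 1874 and 3125 with total counts alone (37.5% rather than 51.9% higher). Without the exa1-1 libraries that held seed storage transcripts, 2480 genes passed.

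Over all 4 conditions, 204 genes were higher and 235 lower in exa1-1 each time, of 20628 tested in all (3.01 and 3.83 if the calls were independent). Of these, 10 and 16 differed by at least 1 on the log2 scale in each condition. The higher ones included the defensin genes PDF1.2, PDF1.2b (AT2G26020), PDF1.2c and PDF1.3. The lower ones included EXA1, FMO1, the camalexin pathway genes CYP71A12 (AT2G30750) and CYP71A13 (AT2G30770), the anion channel gene SLAH1 (AT1G62280) and the terpene synthase gene TPS04 (AT1G61120). These genes were chosen after their values were seen. SLAH1 did not pass under NaCl without replicate 2 of wild type or replicate 1 or 3 of exa1-1 (edgeR, adjusted p = 0.166, 0.115 and 0.104). With FPKM values and limma it did not pass under NaCl or at 39 °C (adjusted p = 0.0927 and 0.317). TPS04 did not pass at 23 °C without replicate 3 of wild type (edgeR, adjusted p = 0.0583). At 39 °C it did not pass without replicate 2 or 3 of wild type (0.168 and 0.0587) or replicate 1 or 3 of exa1-1 (0.133 and 0.0985). Without both exa1-1 libraries that held seed storage transcripts, CYP71A13, TPS04 and SLAH1 did not pass at 39 °C (edgeR, adjusted p = 0.128, 0.0743 and 0.126). In the 1 library left in that group, CYP71A13 was lower by -1.26 and the others had 0 counts. Between the control sets, which share no library, 615 genes were higher and 840 lower in exa1-1 in both (145 and 236 expected from independent lists). The log2 differences of these sets correlated at 0.531 across genes.

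The unstressed control sets were compared, averaged over genotypes. Asparagine synthetase, ASN1 (AT3G47340), was 59.5-fold higher in the 23 °C set than in the 1/2 MS set (5.89 ± 0.14, SE, n = 3 libraries in each of 4 groups). SEN1 (AT4G35770), a dark-induced gene, was 35.1-fold higher (5.13 ± 0.14) and the ferric reductase gene FRO6 (AT5G49730) 45.6-fold (5.51 ± 0.10). The ribonuclease gene RNS1 (AT2G02990), the transcription factor gene RAP2.6 (AT1G43160) and DIR5 (AT1G64160) were lower, with log2 differences of -5.57 ± 0.21, -4.58 ± 0.14 and -5.80 ± 0.28. In all, 16112 of 21262 genes passed (edgeR quasi-likelihood test, BH), 7954 higher and 8158 lower in the 23 °C set, so levels in the salt series were not set against those in the heat series. With total counts alone the median of all genes was shifted by -0.13. The genotype difference itself differed between the sets at 745 genes, 437 higher and 308 lower at 23 °C (695 and 235 with total counts alone, 74.7% rather than 58.7% higher). GH3.3 and the squalene epoxidase gene SQP2 (AT5G24140) differed by 1.70 ± 0.24 and 2.17 ± 0.40, and NRT2:1 and the cell wall gene XTH21 (AT2G18800) by -1.75 ± 0.30 and -2.48 ± 0.25. This count was 281 and 369 without replicate 3 or 1 of wild type at 23 °C, 441 and 445 without replicate 1 or 3 of wild type on 1/2 MS, and 479, 440 and 344 without replicate 1, 2 or 3 of exa1-1 there.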

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

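The tests of time of day and of darkness in this part were chosen after the result was seen; the interaction tests, the other splits of the libraries and the depth test were chosen before. The results given here are differences of responses between exa1-1 and wild type (edgeR's interaction term or camera on it).

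Salt changed the genotypes differently at 2401 genes. The lists that differed were photosynthesis (camera, adjusted p = 1.52e-17), chaperones (9.37e-14), ER unfolded protein response (7.77e-13), ABA and osmotic response (3.85e-09), ethylene (2.63e-05), cell division (0.000808), the clock (0.000982), auxin (0.00102) and salicylic acid with NLR defence (0.0246). Of these only the chaperone call held with an estimated correlation. Responses were higher in exa1-1 for HSP70 (0.70 on the log2 scale), HOP3 (0.71), BIP1 (0.51), CNX1 (0.52), ABI1 (0.74), ERD10 (0.65), EBF2 (0.80), GH3.3 (1.44), PIF4 (1.3) and SAG13 (2.43). They were lower for CAB2 (-1.37), RBCS1A (-0.59), LOX2 (-1.52), SARD1 (-1.11) and ACD6 (-2.56). On 1/2 MS, GH3.3, PIF4 and SAG13 were lower in exa1-1 to begin with. Genotype labels were exchanged within each condition in 100 of 200 possible splits of the libraries, the real split included, and 3 gave as many genes as the real split. The highest other split gave 7022 genes and exchanged all 3 libraries of each genotype under NaCl, so that it added the genotype differences of both conditions in place of subtracting them. Such splits bear on any genotype difference and not on the interaction alone, so they do not decide whether chance gives 2401 genes.

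Heat changed the genotypes differently at 1687 genes. Here the lists were chaperones (camera, adjusted p = 0.000175), seed storage (0.000719), jasmonate (0.00301), ER unfolded protein response (0.0185), mRNA decay and granules (0.0249), EXA1 with its homologues (0.0278), ion transport (0.0373) and heat shock factors (0.0445), and none of these calls held with an estimated correlation. Responses were higher in exa1-1 for HOP3 (0.69), CLPB3 (0.50), HSFA7A (0.90), HSFA2 (1.21) and BZIP28 (0.46). They were lower for EXA1 (AT5G42950; -0.95), PDIL1-2 (-0.60), LTI78 (-1.53), BGL2 (-4.35), OPR3 (-0.63), AOX1A (-0.70) and PRR5 (-0.96). Of 100 splits drawn, 3 gave as many genes as the real one, and the highest other split, with 6465 genes, exchanged all genotype labels at 39 °C, so these do not decide either.

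The genotype difference without stress differed between the control sets at 745 genes, with GH3.3 at 1.70, SQP2 at 2.17, NRT2:1 at -1.75 and XTH21 at -2.48. The splits do not decide for the same reason: 6 of 100 gave as many genes, and the highest other gave 6374. When left out, 7 of the 12 libraries moved the count by over 1.5 times, down to 281. For comparisons of 2 groups there are 10 splits, too few for a share under 0.05, and in each case the real split alone gave its count (1 of 10). The real counts are given above. The highest other split gave 15 genes for genotype on 1/2 MS and 0 for the rest.

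The control sets themselves differed at 16112 of 21262 genes, more than in any other of 100 splits (1 as large, highest other 9448). The tables argue against a difference in depth, because totals overlapped (17658196 to 20690628 counts on 1/2 MS and 17685639 to 20992263 at 23 °C), and thinning each library to the lowest total, which removed few counts, left 15965 calls. The 17 measured clock genes had a median absolute log2 difference of 1.13, at percentile 99.96 of 10000 random lists matched on expression. Any shared shift can give this, so time of day stays open. A list of 21 genes induced by darkness or carbon starvation was higher in the 23 °C set for 19 genes and lower for 1. Its median was 2.21, and 2.19 without ASN1 and SEN1, whose values had been seen. Camera gave p = 2.67e-24, and 0.0174 with an estimated correlation. Photosynthesis took 4.34% and 3.51% of counts (wild type and exa1-1) against 2.06% and 1.66% on 1/2 MS. List and share cannot tell less sugar from less light, so both stay open. Batch entries did not vary, so growth, harvest or sequencing batches stay open.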

How the results depend on the processing

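Leaving out a pair of exa1-1 libraries at 39 °C and leaving out libraries for the correlations were chosen after the result was seen, and the other alternatives before. With relative log expression factors, total counts, DESeq2, no expression filter, organelle genes removed, FPKM values with limma, only the groups compared or the replicate number as a block, all counts of called genes that could be computed were within 1.5 times those reported. Counting only log2 changes of at least 1 lowers a count by construction. It left 4627 and 4983 genes for salt in wild type and exa1-1, 284 for the salt interaction, 397 and 497 for genotype on 1/2 MS and under NaCl, 8742 and 8654 for heat, 258 for the heat interaction, 384 and 527 for genotype at 23 °C and 39 °C, 3966 between the control sets and 93 for its interaction with genotype. Without replicates 2 and 3 of exa1-1 at 39 °C, which held seed storage transcripts, 525 genes passed in the heat interaction and 2480 for genotype at 39 °C. That group then had 1 library, assumed to vary like the others, and fewer samples lower a count. With all 24 libraries in a single model 2557 genes passed in the heat interaction, and the cause was not tested. Of 99 list calls, 27 held with an estimated correlation in place of the preset one, which allows for members that move together. Over called genes only, the salt responses of both genotypes correlated at 0.9406 and the genotype differences of both control sets at 0.6585, with the genes that changed least left out by construction. At 39 °C in wild type, EXA1 (AT5G42950; 0.14, not passed) and AT1G27430 (0.59) were negative with total counts (-0.735 and -0.291 on the log2 scale) and with FPKM values (-0.714 and -0.275). Both moved with the median of all genes, which these scalings shifted by -0.88 and -0.803. Leaving out 1 library gave 965 to 1596 genes for the heat interaction, 2482 to 3670 for genotype at 23 °C, 281 to 919 for the interaction of genotype with control set, and 0.929 to 0.933 for the correlation of the salt responses. The other counts stayed within 1.5 times the reported value when 1 library was left out. Of the member counts of lists computed without 1 library, 50 of 696 moved by over 1.5 times. Of 250 gene values named in the text, 237 kept their direction and their side of the threshold in all alternatives, and of the 3995 values under alternatives, 4 reversed, 30 no longer passed and 1 newly passed. The last was EXA1 at 39 °C in wild type with only the libraries compared (edgeR, adjusted p = 0.0453). With the replicate number as a block, genes called were 15160 and 15339 for salt in wild type and exa1-1, 2335 for the salt interaction, 3710 and 6149 for genotype on 1/2 MS and under NaCl, 16735 and 16742 for heat, 1651 for the heat interaction, 4022 and 5031 for genotype at 23 °C and 39 °C, 15999 between the control sets and 630 for its interaction with genotype. The block ended 2 list calls (camera, jasmonate for genotype under NaCl, adjusted p = 0.0706, and ethylene for genotype at 39 °C, 0.0532) and changed no other call of a list or named gene. The numbers did not pair the libraries, since 0 of 18 same-numbered pairs in each fit had deviations that correlated above 0.1, and 5, 6 and 5 of 12 libraries correlated best with their own number in the salt, heat and control fits. Whether depth or number of replicates limits the recovery of simulated 1.3-fold changes was not tested.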

Other observations

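The tests in this part were chosen after the result was seen, except the first searches for shared sequence, and the genes were chosen after their values were seen. CYP71A12, CYP71A13 and TPS04 were lower in exa1-1 in each of the 4 conditions. CYP71A12 (AT2G30750), a cytochrome P450 of indole metabolism, was lower by log2 differences of -1.90 ± 0.48 on 1/2 MS, -1.65 ± 0.05 under NaCl, -1.48 ± 0.46 at 23 °C and -1.85 ± 0.19 at 39 °C (SE, n = 3 libraries per group). Its neighbour CYP71A13 (AT2G30770), which acts in camalexin synthesis, was lower by -2.35 ± 0.27, -2.76 ± 0.36, -2.13 ± 0.45 and -1.77 ± 0.47 in the same order. The geranyllinalool synthase gene TPS04 (AT1G61120) was lower by -3.49 ± 0.39, -1.30 ± 0.22, -2.86 ± 0.64 and -2.46 ± 0.73. Defensin genes went the other way, with PDF1.3 (AT2G26010) at 0.528 CPM in wild type and 15.3 CPM in exa1-1 on 1/2 MS and at 1.18 and 38.2 CPM at 23 °C, and PDF1.2b (AT2G26020) at 0.0888 and 4.82 CPM at 23 °C. All of these genes passed edgeR's quasi-likelihood test in each condition with all libraries. TPS04 did not pass at 23 °C or 39 °C without some single libraries, as given above. CYP71A13 and TPS04 did not pass at 39 °C without both exa1-1 libraries that held seed storage transcripts. In the 1 library left in that group, CYP71A13 was still lower (-1.26) and TPS04 had 0 counts.

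Clock genes differed between the control sets in both directions. TOC1 (AT5G61380), an evening component of the clock, was higher in the 23 °C set by 1.38 ± 0.05 (log2, SE, n = 3 libraries in each of 4 groups), and LHY (AT1G01060), a morning component, by 1.32 ± 0.23 from a low level. GI (AT1G22770) was lower by -1.48 ± 0.10 and PIF4 (AT2G43010), a growth regulator, was higher by 1.81 ± 0.15. The sugar-repressed genes DIN10 (AT5G20250) and BCAT-2 (AT1G10070) were higher by 2.01 ± 0.08 and 3.95 ± 0.14. Of 17 clock genes measured in this fit, 13 were higher and 3 lower in the 23 °C set (edgeR, BH).

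AT1G64795 and AT2G11405 were counted in all 12 exa1-1 libraries and were at or near 0 in wild type. AT1G64795 had mean counts of 459 ± 80, 1270 ± 55.3, 1537 ± 113 and 474 ± 28.6 (SD, n = 3) in exa1-1 on 1/2 MS, under NaCl, at 23 °C and at 39 °C, against 5 counts in all wild-type libraries together, and was at least 1411-fold higher at 23 °C. AT2G11405 had 103 ± 17.7 on 1/2 MS against 0 in wild type, at least 105-fold higher. The tables argue against reads shared with another locus, since 100% of the 31-base words of each gene occurred once in the reference genome. They argue against antisense reads of the overlapping gene ILA as well, since ILA differed by at most 0.47 (log2) and had 28515 counts in wild type. Genes within 0.5 Mb were called the same way in both control sets about as often as the rest (odds ratio 1.12, 95% interval 0.625 to 1.87; Fisher's exact test, two-sided p = 0.679), which argues against a wide differing segment. A candidate explanation is an insertion or variant at these loci in the mutant line, which was not tested and stays a hypothesis.

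Mitochondrion-encoded transcripts were higher at 39 °C in both genotypes. The TMM factors do not account for it, because the median log2 change was 3.59 in wild type and 3.22 in exa1-1 with total counts alone. A general carry-over of RNA without poly(A) tails would raise chloroplast-encoded transcripts alike, but their median was -0.028 in wild type (quartiles -0.81 and 0.98) and -0.31 in exa1-1, and nuclear rRNA went from 0.00852% to 0.00404% of counts in wild type and from 0.0118% to 0.00412% in exa1-1. Reads shared with nuclear copies in the reference do not account for cox1, nad4L, rps3 and the rRNA genes ATMG00020 and ATMG01390, of whose words at least 90% occurred once and which rose by at least 1.83 (ATMG01390 in exa1-1; 0.84 with total counts), but stay open for the others, since 10 of the 32 measured genes could be matched by symbol. Longer poly(A) tails on mitochondrial transcripts at 39 °C may account for the rise, which was not tested.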
